A study of Escherichia coli with 12 samples.

How the data were processed

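The series measured how LacI variants of Escherichia coli K12 fared in a negative selection. Per the labels' protocols, codons 3 to 359 of lacI (locus tag b0345) were each replaced by 19 missense codons, 6802 sequences in all, in 10 tiles, and the libraries were grown with colicin E1, a concentration of 20.7 ng/mL generally working best, or without it. Amplicons of about 300 bp were sequenced on an Illumina MiSeq. Reads were base called with CASAVA 1.8.2, per the submitters' processing notes. How reads were merged, translated, counted and assigned to variants is not given in the sources used here.

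Titles place the 12 samples in 4 groups of 3 (RV, negRV, WV and negWV). The table has no column per sample, so the groups could not be compared, and it is not known which samples enter each column. The deposited count columns, taken from their names as before and after selection, hold values in steps of 0.5 with no library-size correction by the authors, and 48.9% of variants have a before count that ends in a fraction of 0.5. In every variant both counts are whole or both end in 0.5, for a reason not given in the sources used here. Every variant has a before count of at least 10, or an after count of at least 10 with a before count of at least 1. The deposited ratio column equals the after count divided by the before count, within 1e-09 in all 43669 rows. The authors' score is a straight line in the natural log of that ratio, and every variant lay within 1e-08 of 1 of 16 lines, which were found here from the values. The authors' class is 1 where the score is above 0.5 and 0 below it. These lines define 16 scaling sets. The 10 that hold most single substitutions of a tile are named after it, and the 6 others are called further sets.

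Residues are counted from the first residue of the translated sequence, a valine, and substitutions are written as original residue, position and new residue. For each variant, log2 of (after count + 0.5) over (before count + 0.5) was taken and the log2 ratio of the column totals over all variants, 0.68, was subtracted. The 95% counting interval treats both counts as Poisson. Variants with a before count under 10, 12656 of them, were left out, since all of these were present only with an after count of at least 10. Depletion was a log2 ratio of -1 or less with the interval below 0, and enrichment its mirror.

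Tests were fixed before the data were examined. Position means were taken over single substitutions at positions with at least 5 of them, which left 309 positions, and regions and residue lists were compared with all other positions by two-sided permutation of positions (100000 permutations; 10000 for alternatives). Regions were the headpiece (1 to 45), the hinge (46 to 61), the core N-subdomain (62 to 161 and 293 to 320), the core C-subdomain (162 to 292 and 321 to 329) and the C-terminal linker and helix (330 to 360). The hinge had no position to test, so adjustment ran over 4 regions. The 8 residue lists were DNA contacts, inducer pocket, monomer-monomer interface, tetramerization heptad and wild-type glycine, proline, aromatic and charged residues, and 6 of the 18 DNA contacts, all in the hinge, were not measured. New residues were tested by permuting labels within positions, with Benjamini-Hochberg adjustment over the 20 residues and separately over 2 classes. Correlations across variants carry permutation p-values, medians carry bootstrap intervals from 2000 draws, and shares carry Wilson intervals. Positions and variants are not independent replicates of the experiment.

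Named items followed a rule: the 10 lowest and 10 highest positions by mean log2 ratio among those with at least 10 substitutions, members of the DNA contact and inducer pocket lists, the 5 lowest and 5 highest single substitutions with a before count of at least 100, the unsubstituted protein, and the 5 most substituted variants with a log2 ratio of at least 0 and a before count of at least 100. Positions ranked by the authors' score, the heptad members and the contrasts within the further sets were named after their values were seen. Alternatives changed the minimum count, the pseudocount, the scaling, the limit for depletion, the position summary, the tiles used and the background. Anchoring each scaling set at its ratio for score 1, comparing within tiles, using only single substitutions counted with their own tile, and measuring relative to the unsubstituted protein were added after seeing the data.

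The computations were tested on simulated data. For depletion, simulated counts were placed on the real before counts, with the same ratio for all unchanged variants. Of 100 variants lowered by 2 on the log2 scale, 99.0% were called depleted, as were 100% of 100 lowered by 4, against 0.0779% of 30813 unchanged variants. The region test was run on position values drawn from a normal distribution, without counts. A region of 140 positions lowered by 1 gave a difference of -0.89, and with no region lowered, 7 of 100 runs passed the threshold. Neither simulation held ratio levels that differ between tiles or scaling sets, so these error rates do not cover such differences. All 16 simulated lines were found. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, biopython 1.88 (for BLOSUM62) and matplotlib 3.10.9.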

Results

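LacI, the lac repressor of Escherichia coli, is a tetramer that binds operator DNA and releases it when an inducer sugar is bound. The assay asked which LacI protein variants still held the operator. Cells of the screening strain whose LacI did not bind made TolC, the outer membrane entry point for colicin E1, and were killed by that toxin, so variants that failed to repress were depleted from the surviving pool. The 12 samples fell into 4 groups of 3, which the labels name RV, negRV, WV and negWV without saying what these stand for. The table analysed here has a pair of count columns, read from their names as counts before and after selection, and neither name says which samples it holds. No replicate error could therefore be given, and the intervals on single variants cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

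The table held 43669 protein variants of the 360-residue sequence. There was 1 row without a substitution, 5009 with 1 substitution and 38659 with 2 or more, up to 12. Total counts were 2108234 before and 3370146 after selection. The median before count was 144.5 for single substitutions and 13.5 for multiple substitutions. A before count of at least 10 was reached by 31013 variants, 71.02% of the table, among them 4801 single substitutions. Of the 6783 missense changes possible over codons 3 to 359, 73.8% were present.

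Most single substitutions of LacI stayed close to the level of the pool after selection, and a large minority fell far below it. The median log2 ratio of after to before share was -0.36 (95% bootstrap interval -0.41 to -0.32, n = 4801). Depletion, a log2 ratio of -1 or less with the 95% counting interval below 0, was met by 1558 single substitutions, or 32.5% (95% Wilson interval 31.1 to 33.8). The unsubstituted protein rose, with 4625.5 counts before and 9478.5 after and a log2 ratio of 0.36 (95% counting interval 0.31 to 0.41). In the authors' deposited table its score was 1.11. The row of the unsubstituted protein lay in the scaling set of tile 1, so its level is a reference for that set only. Enrichment by the mirrored rule was met by 166 single substitutions, or 3.46% (95% Wilson interval 2.98 to 4.01), of which 68.1% were counted with tile 10 and 24.7% with tile 2, tiles being the 10 stretches of the gene that were mutated separately. Among multiple substitutions, 42.8% were depleted (95% Wilson interval 42.2 to 43.4, n = 26211). Over all variants together the share was 41.2%, and its order against that of single substitutions depended on the count minimum and the limit. With a minimum of 50 counts 29.4% of all variants were depleted (95% Wilson interval 28.5 to 30.4) against 31.7% of single substitutions (95% Wilson interval 30.3 to 33.2). With no minimum the shares were 29.2% and 31.1%. These falls from the main shares were fixed by the filter, since every variant with a before count under 10 had an after count of at least 10. None of those could reach a log2 ratio of -1, so they only enlarged the total. With the interval alone as the limit the shares were 46.5% and 49.0%. The authors' class 0, a score below 0.5, held 27.7% of single substitutions (95% Wilson interval 26.4 to 28.96) and 36.5% of multiple substitutions (95% Wilson interval 35.9 to 37.1).

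The level of the log2 ratio differed between parts of the library. The authors' score was a straight line in the natural log of the ratio, with 16 different lines, 10 of them for the tiles and 6 for further sets of variants. The ratio at which the score reached 1 ran from 0.831 in tile 9 to 11.2 in tile 2, a 13.4-fold range, whereas the ratio at score 0 lay between 0.102 and 0.195 in every set. Log2 ratios of high variants in different tiles are therefore not on 1 scale, and the authors' score is given beside them. The fixed depletion limit of -1 is affected too. Single substitutions of tile 9 had a median log2 ratio of -0.95 at a median score of 0.98, and those of tile 10 had 0.51 at 0.89. In tile 9 the limit thus lay close to score 1, and variants could be called depleted without being in class 0. Anchoring every set at score 1 moved the median of single substitutions to -0.16.

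The single substitutions most depleted among those with a before count of at least 100 were acidic or alanine replacements in the core. E100D had the lowest log2 ratio, -4.70 (95% counting interval -5.12 to -4.28), with 787 counts before and 48 after. The position itself was tolerant, with a mean of -0.53 ± 1.21 (SD, n = 17 substitutions), and E100D was its only substitution in class 0. R326A followed at -4.61, Q248D at -4.57, H179A at -4.56 and V270D at -4.54, and their scores in the authors' deposited table ran from -0.433 to -0.146. The highest log2 ratios were all at H74, a residue of the core N-subdomain near the dimer interface. H74C rose by 3.88 on the log2 scale (95% counting interval 3.76 to 4.01), from 524.5 to 12385.5 counts. H74F, H74Y, H74I and H74S rose by 3.66, 3.58, 3.56 and 3.49. These belong to tile 2, the tile with the highest ratio at score 1, and the authors' deposited table gave them scores of 1.19, 1.15, 1.13, 1.13 and 1.12.

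Substitutions at a few glycine, proline and charged positions of the core were depleted almost without exception. Over the 269 positions with at least 10 measured substitutions, R326 had the lowest mean log2 ratio, -4.04 ± 0.42 (SD, n = 11 substitutions), and all 11 were depleted. G252 lay at -3.97 ± 0.22 (SD, n = 19), and its 19 substitutions were all depleted. G297 followed at -3.94 ± 0.76 (SD, n = 13), P284 at -3.72 ± 0.42 (SD, n = 19), H179 at -3.67 ± 1.14 (SD, n = 13) and G272 at -3.67 ± 0.62 (SD, n = 19). G166, D247, Y282 and P285 completed the lowest 10, with means of -3.55, -3.51, -3.50 and -3.47. R326 and G297 belong to tile 9, the tile with the lowest ratio at score 1. With tile totals, centring on the 75th percentile within tiles and anchoring at score 1, R326 moved to -3.27, -3.37 and -3.10 and G297 to -3.16, -3.27 and -3.00. Both then left the lowest 10, and G252 was lowest with each of these 3 scalings. Y282 lies in the interface between monomers. By the authors' score, 9 of these 10 positions were again among the lowest 10, where R22, an operator-contacting arginine of the recognition helix, took the place of G166 with a mean score of 0.0329 ± 0.119 (SD, n = 19). Every measured substitution was in class 0 at 4 positions, R22, G252, P284 and R326.

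The highest positions depended on the scale. By log2 ratio, H74 led at 2.50 ± 1.32 (SD, n = 14), followed by A337 at 1.09 ± 0.29 (SD, n = 12), N333 at 1.07 ± 0.40 (SD, n = 13) and P332 at 0.96 ± 0.56 (SD, n = 13). S358, S345, A341, T334, T336 and L330 had means from 0.79 to 0.90, and 9 of the 10 highest positions lay in tile 10. By the authors' score none of these 10 was among the highest 10, which were A32, T299, S28, A266, L73, Y12, K325, V238, K108 and S260. A32, in the headpiece, had a mean score of 1.12 ± 0.0546 (SD, n = 19) and A266, in the core, 1.09 ± 0.0455 (SD, n = 19). At 90 of the 269 positions no measured substitution was in class 0.

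**Figure D1:**
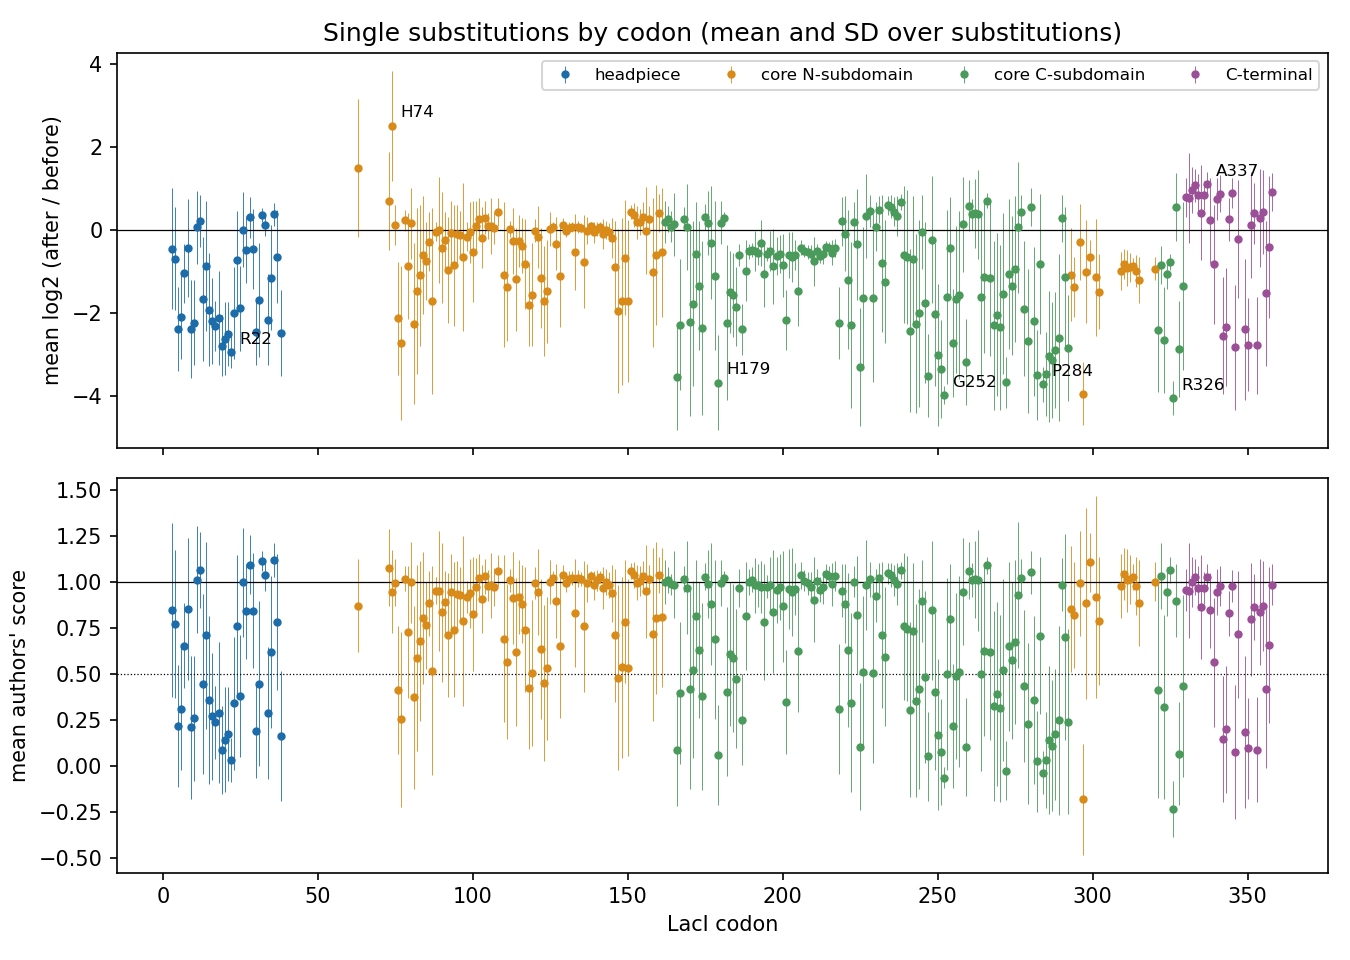
Mean log2 ratio of after to before share (top) and mean authors' score (bottom) of single substitutions against LacI codon, for the 309 positions with at least 5 substitutions, coloured by region. Points are means and bars are SDs over substitutions, the solid lines mark a log2 ratio of 0 and a score of 1, and the dotted line marks a score of 0.5. R326 and G252 sit lowest by log2 ratio at -4.04 and -3.97, and C-terminal positions such as A337 lie above 0 in the top panel and near 1 in the bottom panel.

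The DNA-binding headpiece and the C-terminal subdomain of the core were the parts of LacI with the lowest ratios, and of the 4 regions tested the N-terminal subdomain of the core had the smallest share of substitutions in class 0. Position means averaged -1.34 ± 1.06 in the headpiece (SD, n = 36 positions), -1.15 ± 1.24 in the core C-subdomain (SD, n = 140), -0.51 ± 0.85 in the core N-subdomain (SD, n = 105) and -0.24 ± 1.39 in the C-terminal linker and helix (SD, n = 28). In two-sided permutation tests of each region against all other positions, the headpiece differed by -0.54 (adjusted p = 0.00967) and the C-subdomain by -0.51 (adjusted p = 0.0003). The 36 headpiece positions tested were codons 3 to 38, which are all of tile 1, so their log2 difference cannot be told apart from that tile's ratio level. The N-subdomain was higher by 0.55 (adjusted p = 0.0003) and the C-terminal region by 0.69 (adjusted p = 0.0038) in these permutation tests. With tile means subtracted and positions permuted within tiles, the N-subdomain differed by 0.13 (adjusted permutation p = 0.0473) and the C-subdomain by -0.15 (adjusted permutation p = 0.0431). The C-terminal region differed by 0.10 (adjusted permutation p = 0.308), and its tile held only K327, T328 and T329 from another region. Tiles that hold a single region add nothing to these values, so their size cannot be set against the differences above. The C-terminal difference turned negative on the authors' score, at -0.0205 (adjusted permutation p = 0.749), and with the other 3 scalings by tile or scaling set. With those 3 scalings the headpiece call was also lost, with differences of -0.43, -0.38 and -0.42 (adjusted permutation p = 0.0529, 0.0923 and 0.0589). On the authors' score the headpiece still differed, by -0.195 (adjusted permutation p = 0.00122). Class 0 held 48.4% of headpiece substitutions (95% Wilson interval 44.4 to 52.4, n = 591) and 14.8% of those in the N-subdomain (95% Wilson interval 13.1 to 16.7, n = 1447). The hinge helix, which inserts into the operator minor groove, had 27 single substitutions with a before count of at least 10 and no position with 5, so it was not tested. Of these 27 substitutions 0 were in class 0, which would allow a share of up to 11.1% if they were representative. Of the 106 such single substitutions of tile 2, which spans the hinge, only 46 were counted with the tile's own scaling set. Single substitutions counted outside their own set were in class 1 in 95.2% over all tiles. Tolerance of the hinge can therefore not be read from these values.

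Operator-contacting residues, the leucine heptad that joins dimers into tetramers and wild-type glycines were the residue groups with lower ratios. The 12 measured DNA contacts averaged -1.98 ± 0.66 (SD over positions) against -0.83 ± 1.17 at the other 297 positions, and the two-sided permutation test gave an adjusted p of 0.00648. All but H29 lay below the mean of the other positions. R22 was lowest at -2.95 ± 0.39 (SD, n = 19), S21 lay at -2.51, T5 at -2.39 and Y17 at -2.32, while H29 lay at -0.46 ± 0.96 (SD, n = 18). With each region's mean subtracted and positions permuted within regions, the contacts differed from all other positions by -0.67 (adjusted permutation p = 0.0249). The heptad positions L342, L346, L349, V353 and L356 had means of -2.55, -2.83, -2.40, -2.78 and -1.53. As a group they differed by -1.57 from all other positions (adjusted p = 0.00843, permutation test). With region means subtracted and positions permuted within regions, the difference from all other positions was -2.21 (adjusted permutation p = 0.0016). Wild-type glycines averaged -1.64 ± 1.48 over 19 positions, with 14 below the mean of the others (adjusted permutation p = 0.00843), a call that ended after anchoring (adjusted p = 0.0574), after centring on the 75th percentile within tiles (adjusted p = 0.0515) and without tile 5 (adjusted p = 0.0709).

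The mean ratio at residues that line the inducer pocket did not differ from that of other positions past the threshold. Their 17 positions averaged -0.70 ± 0.77 against -0.88 ± 1.19 elsewhere (adjusted p = 0.62, two-sided permutation test), and their class 0 share was 20.6% (95% Wilson interval 16.2 to 25.9) against 28.7% at other positions (95% Wilson interval 27.3 to 30.0). These intervals do not overlap, but they count substitutions of a position as independent, and over position means the score differed by 0.0784 (adjusted permutation p = 0.442). Within the pocket P76 was lowest, at -2.13 ± 1.35 (SD, n = 15), followed by N246 at -1.75 ± 1.94 (SD, n = 18) and L148 at -1.72 ± 2.02 (SD, n = 11). D274, which hydrogen-bonds the inducer, lay at -1.34 ± 1.67 (SD, n = 19) and R197, another inducer contact, at -0.87 ± 0.90 (SD, n = 19). N125, R101 and L73 lay at 0.010, 0.08 and 0.69. The monomer-monomer interface differed from the other positions by -0.36 (adjusted permutation p = 0.389), a difference that reached -1.11 without tile 3 (adjusted p = 0.0326). Wild-type aromatic positions differed by -0.35 (adjusted permutation p = 0.389), wild-type prolines by -0.12 (adjusted p = 0.709) and wild-type charged positions by 0.31 (adjusted p = 0.139), none past the threshold over all positions. The charged positions passed it when compared within tiles (0.40, adjusted permutation p = 0.0237) and without tile 9 (0.44, adjusted permutation p = 0.0284).

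Proline, aspartate, tryptophan and glutamate were the least tolerated new residues, and cysteine, serine, alanine and methionine the best tolerated. Within positions, proline substitutions deviated from their position mean by -0.83 ± 0.09 (SE, n = 211), aspartate by -0.56 ± 0.07 (SE, n = 261), tryptophan by -0.44 ± 0.06 (SE, n = 229), glutamate by -0.42 ± 0.07 (SE, n = 204) and lysine by -0.30 ± 0.07 (SE). Cysteine deviated by 0.58 ± 0.06 (SE, n = 277), serine by 0.51 ± 0.07 (SE, n = 247), alanine by 0.46 ± 0.06 (SE, n = 235), methionine by 0.39 ± 0.06 (SE, n = 256) and threonine by 0.31 ± 0.06 (SE, n = 217). In two-sided permutation tests within positions, 6 residues were lower and 6 higher after adjustment over the 20, and 8 did not pass. Arginine and valine were the weakest of those that passed, at -0.18 and 0.20. As a class, charged substitutions lay -0.37 from their position means (n = 897) and conservative ones, with a BLOSUM62 score of at least 1, lay 0.68 above them (n = 551), each at the smallest adjusted p the permutations can give, 1e-05. Class 0 held 53.6% of proline substitutions (95% Wilson interval 46.8 to 60.2) and 7.62% of conservative ones (95% Wilson interval 5.69 to 10.1).

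**Figure D2:**
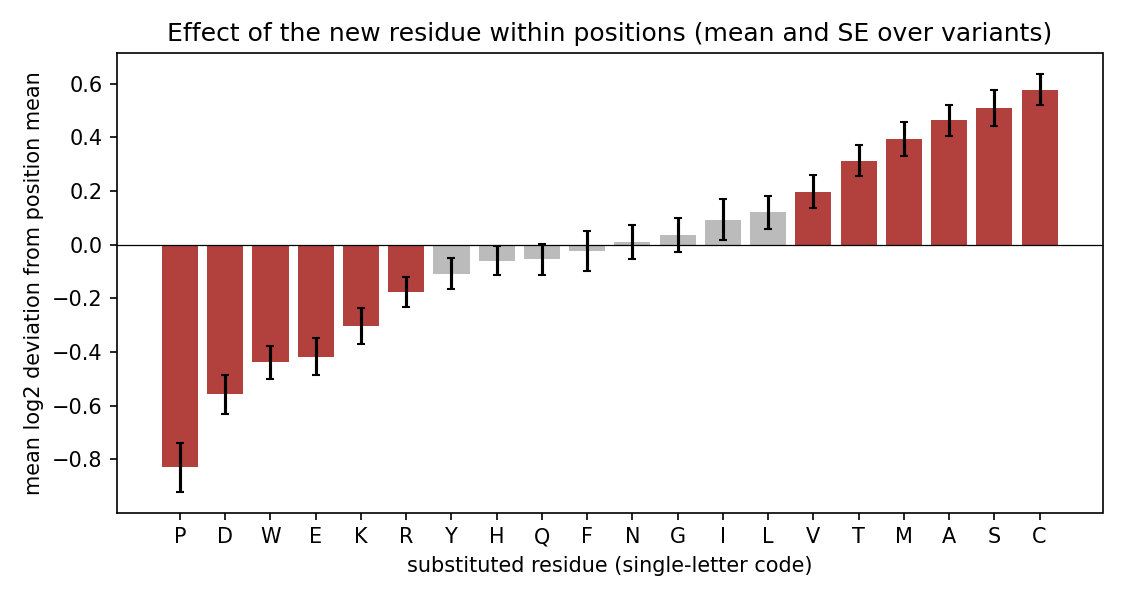
Mean log2 deviation of single substitutions from the mean of their position, by substituted residue, with bars of 1 SE over variants. Red bars passed the adjusted permutation test and grey bars did not; proline is lowest at -0.83 and cysteine highest at 0.58.

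Variants with 6 or more substitutions repressed less often than those with fewer, although some with 7 or 8 substitutions still did. The share in the authors' class 1 was 72.3% with 1 substitution (95% Wilson interval 71.04 to 73.6, n = 4801), 65.2% with 2 (95% Wilson interval 64.3 to 66.1, n = 10635), 67.6% with 4 (95% Wilson interval 66.2 to 68.96, n = 4365), 57.6% with 6 (95% Wilson interval 55.4 to 59.8, n = 1926), 39.9% with 7 (95% Wilson interval 36.5 to 43.5, n = 736) and 28.6% with 8 (95% Wilson interval 22.8 to 35.3, n = 199). Median log2 ratios were -0.83 with 2 substitutions, -0.30 with 4, -0.31 with 5, -2.26 with 7 and -2.68 with 8. Across all variants, which are not independent replicates, Spearman's rho between number of substitutions and log2 ratio was 0.0332, and it was -0.0974 with the authors' score (each with the smallest two-sided permutation p possible, 1e-05). With a minimum before count of 50 the rho with log2 ratio was 0.229. Within the 16 scaling sets rho was negative in 14 and positive in 2, with a median of -0.208, and 12 of the negative values passed adjustment.

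**Figure D3:**
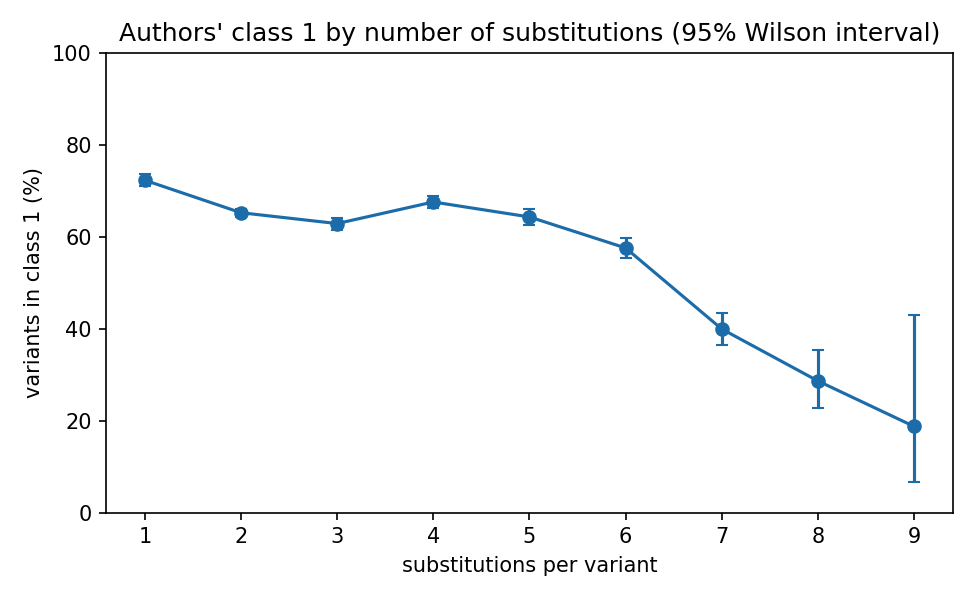
Share of variants in the authors' class 1 (percent) against the number of substitutions per variant, with 95% Wilson intervals, for variants with a before count of at least 10. The share falls from 72.3% with 1 substitution to 39.9% with 7 and 28.6% with 8.

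The 6 further sets held 20120 variants. Each set is described by its 8 most often substituted sites. A first pair of sets shared L73, A75, P76, I79, H112, N113 and N125, with I124 in one list and M98 in the other. Another pair shared L148, I160, F161, H163, S193, L196 and R197, with D149 in one list and G166 in the other. The last pair shared A245, Y273, Q291, F293 and L296, with M249, D274 and T276 in one list and N246, I289 and K290 in the other. Within the largest, of 5306 variants, those that carried a G166 substitution were in class 1 in 35.4% (95% Wilson interval 32.1 to 38.8, n = 775), against 79.7% of those that did not (95% Wilson interval 78.4 to 80.97, n = 3849). Among variants of another set, 67.8% with a D274 substitution were in class 1 (95% Wilson interval 65.4 to 70.1, n = 1502) and 11.8% without (95% Wilson interval 9.05 to 15.1, n = 434). These contrasts do not hold the other substitutions of a variant fixed. The most substituted variants with a log2 ratio of at least 0 and a before count of at least 100 included A245D/M249Q/Y273R/D274G/T276N/Q291E/F293Y/L296Q, with 8 substitutions, at 1.21 (95% counting interval 0.92 to 1.496) but at -0.29 with anchored scaling. The same chain with L296I in place of L296Q lay at 0.20 (95% counting interval -0.12 to 0.51) but at -1.30 with anchored scaling, and without a change at L296 it lay at 1.25 but at -0.24 with anchored scaling. S162N/H163Y/G166A/P188D/S193G/R197L lay at 0.15 (95% counting interval -0.09 to 0.40) but at -0.26 with anchored scaling, and Y273F/D274G/T276N/Q291V/F293Y/L296I at 1.95 and 0.45 in the same order. In the authors' deposited table these 5 had scores of 0.944, 0.746, 0.953, 0.932 and 1.09.

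The effects of single substitutions carried over in part to the variants that combined them. For the 21783 multiply substituted variants whose single substitutions were all measured, the observed log2 ratio correlated with the sum of the single ones at Pearson's r = 0.571 and Spearman's rho = 0.551 across variants (each with the smallest two-sided permutation p possible, 1e-05). The lowest of the single log2 ratios alone gave Pearson's r = 0.538, so the correlation is not evidence that effects sum. In tile 8 the lowest gave 0.826 against 0.761 for the sum, and in some other sets the sum gave the higher r. Pearson's r with the sum was 0.720 for variants with 2 substitutions (n = 9475), 0.447 with 4 (n = 3649) and 0.252 with 8 (n = 122). By set, r was highest in tile 8, at 0.761. It was lowest in tile 2 (n = 209) and in the largest further set (n = 3589), both at 0.220. The median of observed minus summed values depends on where the scale has its 0. It was -0.69 (95% bootstrap interval -0.71 to -0.66) with 0 at the ratio of the column totals and 0.014 with 0 at the unsubstituted protein, a scale chosen after seeing the data, so its sign does not bear on additivity.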

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

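The tests on tile 2 were chosen after the result was seen. The tests on the number of substitutions and on doubly substituted variants were fixed before the values they measure were computed.

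Counts appeared at codons 1 and 2, which the library design left unmutated, above the 3 counts that a count of 0 allows. Before counts were 64.5 for K2R, 44 for K2E, 20 for V1A, 11 for K2I, 9.5 for V1M and 8.5 for K2N. After selection these had log2 ratios of -0.01, -0.23, 0.12, -1.50, -0.30 and 0.15 in the same order.

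Variants with 4 or 5 substitutions had a median log2 ratio 0.52 above that of variants with 2 (95% bootstrap interval 0.47 to 0.62). With a before count of at least 50 the difference was 0.85 (95% bootstrap interval 0.74 to 0.96), which speaks against low before counts as its source. After each scaling set's median was subtracted the difference was 0.048 (95% bootstrap interval -0.019 to 0.11). Sets that differ in both ratio level and number of substitutions may therefore account for it. The subtraction cannot show this, because it removes any difference that lies between sets, whatever its cause. Some sets held few variants with 2 substitutions, such as a further set where 25 of 944 had 1 or 2. No biological explanation was tested.

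Variants of the tile sets with 2 substitutions were less often in class 1 when either of their single substitutions was in class 0. A second substitution read from a sequencing or PCR error may contribute, since such an error would leave the variant with the class of the intended substitution. Among 146 variants whose substitution inside the tile was in class 1 and whose substitution outside it was in class 0, 42.5% were in class 1 (95% Wilson interval 34.7 to 50.6). This interval holds 50%, so it does not settle whether most of them kept the class of the substitution inside the tile. With the classes exchanged the share was 12.2% (95% Wilson interval 6.76 to 21.01, n = 82), and with both in class 1 it was 87.5% (n = 543). The first 2 intervals do not overlap, so the class followed the substitution inside the tile more closely. That is the direction such errors would give, but other sources of the difference were not tested. No biological explanation was tested.

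Single substitutions of tile 2, which spans the hinge, were almost all in class 1. Among those with a before count of at least 10 the share was 95.3% (95% Wilson interval 89.4 to 97.97), against 71.8% in the other tiles (95% Wilson interval 70.5 to 73.1), which speaks against the filter on after counts for low before counts as the source. Within the tile's own scaling set it was 93.5% (95% Wilson interval 82.5 to 97.8, n = 46), still above the other tiles. Counting with other sets therefore cannot account for the high share among these 46. The rest of the tile's 106 substitutions were counted with other sets, so this test does not cover them. It does not bear on the hinge either, since L73 and H74, outside it, held 17 and 14 of the 106. How many of the 46 lie in the hinge was not tested. Tile 2 held 24.0% of its designed substitutions, the lowest share of the 10 tiles, and which ones are missing was not tested. No biological explanation was tested.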

How the results depend on the processing

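No paired analysis was possible because the columns carry no replicate number. For the same reason the planned per-sample count test, its other tool, the replicate block, leaving out replicates and a joint fit of RV and WV were not run. Anchored scaling, comparison within tiles, use of substitutions counted with their own tile and values relative to the unsubstituted protein were chosen after seeing the data. Of 371 values of the main results recomputed under alternatives, 27 moved, 13 reversed, 7 lost the threshold and 3 gained it. The others kept their direction and side of the threshold, stayed within their interval or, for counts of residues, stayed within 1.5 times the count. Of these counts 1 changed, that of residues with higher effects, from 6 to 5 with a minimum count of 50. Of 280 values of named positions and variants, 169 stayed within their interval, 85 moved and 26 reversed. Leaving out tile 1 or tile 10 removed all measured members of the headpiece and its DNA contacts or of the C-terminal region and its heptad, so these gave no value, and within tiles the headpiece had none to compare with. Depth limits multiple substitutions most, at a median before count of 13.5. Where no cause is named, the cause was not tested.

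The median of single substitutions was -0.29 with no minimum count, -0.012 with totals within each tile, -0.31 with centring on the 75th percentile of single substitutions within each tile and -0.16 with anchored scaling. It was -0.0471 on the authors' score, counted from 1. The depleted share of single substitutions was 31.1% with no minimum count, 30.5% with tile totals, 35.1% with the 75th percentile and 27.7% with the authors' class. Dropping the minimum lowers the share by construction, here and for all variants, since no variant it adds could be depleted. Limits of -2 and of 0 gave 25.8% and 49.0%, by their construction. For all variants the share was 29.4% with a minimum count of 50, 29.2% with no minimum, 51.8% with the 75th percentile, 35.1% with the authors' class, 43.7% with anchored scaling, 30.8% with a limit of -2 and 46.5% with a limit of 0.

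The rho between number of substitutions and effect reversed to -0.0385 with tile totals, -0.0616 with the 75th percentile, -0.0974 with the authors' score, -0.128 with anchored scaling and -0.172 in variants confined to 1 tile, and with a minimum count of 50 it was 0.229. The C-terminal region reversed to -0.089 with tile totals, -0.072 with the 75th percentile, -0.0205 with the authors' score and -0.24 with anchored scaling. With tile means subtracted its difference was 0.10 and no longer passed, but its tile held only K327, T328 and T329 from another region. With tile means subtracted the N-subdomain differed by 0.13 and the C-subdomain by -0.15, both past the threshold. Tiles of a single region add nothing to these values, so they do not show a smaller effect. The headpiece no longer passed with tile totals (-0.43), the 75th percentile (-0.38) and anchored scaling (-0.42), but passed with the authors' score (-0.195). Tile totals and the 75th percentile remove part of its difference by construction, since it fills its tile. Wild-type glycine no longer passed with the 75th percentile (-0.65), with anchored scaling (-0.62) and without tile 5 (-0.66). The monomer-monomer interface passed without tile 3 (-1.11), and wild-type charged positions passed without tile 9 (0.44) and within tiles (0.40). Among lists that did not pass, wild-type proline turned to 0.025 without tile 3 and 0.28 without tile 8, and the inducer pocket to -0.24 with substitutions counted with their own tile.

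The median of observed minus summed effects was -0.45 with a minimum count of 50, -0.50 with no minimum, -0.66 with a pseudocount of 1, -0.58 with a pseudocount of 5, -1.24 with tile totals, -0.61 with the 75th percentile, -0.176 with the authors' score, -0.64 with anchored scaling and -0.53 with exactly 2 substitutions. Relative to the unsubstituted protein it reversed to 0.014, by construction, since its sign depends on the 0 of the scale.

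Named positions that reversed were all among the highest. With the 75th percentile they were H74 (-0.24), S358 (-0.054), S345 (-0.077), A341 (-0.084), T334 (-0.12), T336 (-0.13) and L330 (-0.17). On the authors' score, counted from 1, they were H74 (-0.0497), S358 (-0.0129), S345 (-0.0176), A341 (-0.0206), T334 (-0.0284), T336 (-0.0312) and L330 (-0.0411). With anchored scaling they were H74 (-0.30), P332 (-0.0069), S358 (-0.062), S345 (-0.085), A341 (-0.091), T334 (-0.12), T336 (-0.13) and L330 (-0.18). Of variants whose interval excluded 0, A245D/M249Q/Y273R/D274G/T276N/Q291E/F293Y/L296Q reversed to -0.0557 on the score and -0.29 with anchored scaling, and A245D/M249Q/Y273R/D274G/T276N/Q291E/F293Y to -0.0470 and -0.24. Of those whose interval held 0, the chain ending in L296I turned to -0.35 with the 75th percentile, -0.254 on the score and -1.30 with anchored scaling, and S162N/H163Y/G166A/P188D/S193G/R197L to -0.24, -0.0678 and -0.26. The 10 lowest positions shared 7 to 10 members with the main list under every scaling, count minimum and pseudocount tried.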

Other observations

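Tolerated and depleted positions lay close together in the helix that joins LacI dimers. Of the 5 heptad positions, L346 had a mean score of 0.0764 ± 0.366 (SD, n = 18 substitutions), V353 0.0886 ± 0.286 (SD, n = 18), L342 0.148 ± 0.342 (SD, n = 17), L349 0.185 ± 0.413 (SD, n = 9) and L356 0.421 ± 0.433 (SD, n = 12). Of positions outside the heptad, named after their values were seen, A350 and A343 were as low, with mean scores of 0.0963 ± 0.272 (SD, n = 13) and 0.201 ± 0.346 (SD, n = 19), and 12 and 15 of their substitutions in class 0. A341 had a mean score of 0.979 ± 0.109 (SD, n = 15) and S345 of 0.982 ± 0.0877 (SD, n = 10). These positions belong to the same tile and scaling set.

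Single substitutions counted outside the scaling set of their own tile numbered 208, of which 116 were in a further set. With a before count of at least 10, 95.2% of these were in class 1 (95% Wilson interval 90.8 to 97.6, n = 167), against 71.5% of single substitutions in their own set (95% Wilson interval 70.2 to 72.8, n = 4634). The 6802 designed sequences named in the labels exceed the 6783 missense changes that 357 codons with 19 replacements give.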
